A study of Mus musculus with 120 samples.

How the data were processed

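Mouse embryonic fibroblasts (MEFs, connective tissue cells grown from embryos) of 3 genotypes were analysed: wild type (WT), cells whose eIF2α carries the S51A substitution and so cannot be phosphorylated at that site by PERK, and cells labelled ATF4-/-. Thapsigargin, an inhibitor of the calcium pump of the endoplasmic reticulum (ER), was added at 1 µM for 0.5, 1, 2 or 4 h, and untreated cells were taken as 0 h. Per the labels' protocols, cells were opened with digitonin and then with DDM to give a cytosol and an ER fraction, ribosome footprints were made with micrococcal nuclease, and mRNA was depleted of ribosomal RNA and fragmented before a directional small RNA library preparation. The labels list 120 samples in 60 groups, which are 3 genotypes, 2 fractions, 2 kinds of library and 5 times with 2 libraries per group. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. By that protocol both fractions come from the same cells, and the titles number their replicates alike, except untreated WT mRNA (1 and 2 in cytosol, 2 and 3 in ER).

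The authors deposited a table of footprint levels and a table of mRNA levels, each with 22417 genes. Per the file headers, each holds a total level per gene, genotype and time, and a fraction on the ER. The deposited totals are in RPKM, which was read from the values, because no header names the unit. Replicates and fractions had been pooled by the authors: a total is the ER level plus the cytosol level, each averaged over the replicates with reads and scaled by a weight of its fraction. The deposited fraction on the ER is the ratio of the ER level to that total. Bowtie 1.1.1 and cutadapt 1.6 are named in the submitters' processing notes. Their settings and the genome build are not given in the sources used here. In the WT footprint columns the smallest level corresponds to 4 reads in a replicate, so a gene under that minimum is listed at 0.

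Levels of single libraries were computed from these pooled values, because the deposited numbers keep many digits. A total multiplied by the deposited fraction on the ER, or by its complement, and by the coding length is a sum of 2 whole-read numbers, each times the worth of 1 read in its library. The worth of 1 read was estimated per library from genes with few reads, and the pair of whole numbers was then solved per gene, to a relative tolerance of 7e-12. Coding lengths came from the GENCODE annotation of GRCm38 and existed for 20238 genes, 90.3% of the table. Of the footprint values per fraction, 363113 of 370551 were solved, 98.0%, and of the mRNA values 248377 of 254301, 97.7%. With coding lengths exchanged between genes, 56 of 14926 footprint values (0.38%) and 49 of 13812 mRNA values (0.35%) were solved. The summed levels of the 2 libraries of a group, which were not forced to be equal, had a median ratio of 1.006 for footprints and 1.083 for mRNA, and the largest ratios were 1.05 and 1.26. The mRNA columns of the libraries labelled ATF4-/- resolved into 1 library per group, so they give values with no test. All SDs, n and p-values rest on these recovered libraries, and the authors' own pooled totals are given without SD or n. The recovered levels keep the authors' fraction weights. The recovered libraries carry no replicate number, so fractions could not be paired and were modelled as separate samples. Standard errors and p-values of averaged changes and shifts therefore leave out error that both fractions share. The library of a group in which 1 read is worth less RPKM is called a, and the other b. Library a also has more reads, except for mRNA in cytosol of S51A at 2 h and of WT at 2 h and 4 h. Genes with no solution in a group, among them very abundant ones, have no library value there, and Xbp1 has none at all.

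Recovery was tested on simulated data for 6 groups, at depths that may lie below the real ones. Of the values 95.09% to 100% were solved, and 100% of these were right.

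Depth is the number of recovered reads of a library on the genes used, 20053 for footprints and 20169 for mRNA. Footprint libraries held a median of 1899085 reads in WT, 7928434 in S51A and 4455939 in libraries labelled ATF4-/-. mRNA libraries were far shallower, and most genes in them lie under the 20 predicted reads used below as a depth filter. Replicates were compared by a chi-square test of their reads over genes. The statistic per degree of freedom lay between 1.33 and 85.4 in the groups with 2 libraries, so no library was counted as deposited a second time.

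The tables hold normalized values, so the branch of the design for such values was used. Differences were tested with limma 3.58.1 (trend and empirical Bayes moderation) in R 4.3.3 on log2(RPKM + 1), so every log2 change is on that scale, which understates changes of low genes. Genes needed a level of at least 1 in at least 10 libraries, which left 10421 genes for footprints, 10600 for mRNA and 9492 for both. All 60 footprint libraries, 50 mRNA libraries or both together entered 1 model with a mean per group, so that groups of 2 shared an estimate of the spread, with 30, 20 and 50 residual degrees of freedom. Each change is the mean of the change in the ER fraction and that in the cytosol fraction. Translational efficiency was tested in 1 model over both kinds of library, as the footprint change minus the mRNA change. A genotype difference is the change in S51A or in libraries labelled ATF4-/- minus the change in WT. A shift is the change of the log2 ratio of the ER to the cytosol level. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. There were 25 tested comparisons, and 7 others, all on mRNA of the libraries labelled ATF4-/-, were not tested.

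There were 32 gene lists: 24 pathways or complexes, 7 sets of cell type markers (endothelial, epithelial, fibroblast, macrophage and leukocyte, muscle and myofibroblast, neural, pluripotent), and the genes the authors' tables mark as ER-targeted. How the authors chose the last list is not given in the sources used here, so its direction is not independent evidence if these samples were used. Lists with at least 3 measured members were tested against the other genes with camera at a preset correlation of 0.01, in 741 list tests adjusted together, and again with an estimated correlation. Pluripotency markers had too few measured members in every comparison. Within a list, calls were also adjusted over the list alone.

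Named genes followed a rule. For each comparison these were the 6 largest rises and 6 largest falls with an adjusted p under the threshold, the same direction in both fractions and all replicates, and a mean level at or above the median of tested genes, leaving out gene models without a usual symbol. Added to these were up to 4 called members, by smallest adjusted p, of each list that passed its test or had at least 3 called members. Named in any case were Atf4, Eif2s1, Ddit3, Atf3, Trib3, Chac1, Asns, Ppp1r15a, Hspa5, Hsp90b1, Herpud1, Xbp1, Dnajb9, Sdf2l1, Bloc1s1, Col1a1, Fn1, Gapdh and Actb.

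Calls were tested on simulated reads at the real depths and levels, with 200 genes changed 1.5-fold, 2-fold or 4-fold. All libraries shared a dispersion of 0.03, but real pairs differed in noise, so the shares of unchanged genes below may be too low. For WT at 1 h, which includes shallow libraries with the minimum of 4 reads, 198 of 314 simulated calls over 10188 genes were unchanged genes (63.1%). Among the 2768 genes with at least 20 predicted reads in every compared library, it was 6 of 49 (12.2%), and 93.3% of 2-fold and 100% of 4-fold changes were found. Counts for WT at 1 h are therefore also given for such genes. For WT at 4 h 8 of 102 simulated calls were unchanged genes, for S51A 1 of 103 at 1 h and 1 of 96 at 4 h, and for the libraries labelled ATF4-/- 3 of 97 at both times. For mRNA in WT the simulation without the depth filter called no gene of any fold at 1 h or 4 h, so a low count there says little. With the filter 1 of the 2 genes changed 4-fold was called at 1 h (361 genes) and none at 4 h (357 genes).

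Alternatives were a TMM-type rescaling of each library, no filter on low values, a pseudocount of 0.25, and leaving out each library in turn. After seeing the data, 3 more were added. They were limma voom on the recovered reads, the filter of 20 predicted reads, and leaving out the 8 shallowest libraries, listed below. The design, the gene lists, the naming rule and the first 4 alternatives were fixed before the data were examined. Positions are those of GENCODE on GRCm38. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.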

Results

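Ribosome footprints and mRNA were measured in MEFs with wild-type eIF2α (WT), with eIF2α that cannot be phosphorylated (S51A), or labelled ATF4-/- with intact eIF2α. PERK is the ER stress sensor that phosphorylates eIF2α. This lowers translation initiation and favours the mRNA of ATF4, a transcription factor of amino acid and stress genes. Cells were treated with 1 µM thapsigargin, which impairs protein folding in the ER, and an ER and a cytosol fraction were taken at 0, 0.5, 1, 2 and 4 h. mRNA of cells labelled ATF4-/- (1 library per group) was not tested. Footprint libraries held 298970 to 11095518 reads in WT, 6229493 to 15168740 in S51A and 2023324 to 8708674 in libraries labelled ATF4-/-. mRNA libraries held 56947 to 118514, 667 to 556027 and 207 to 300930 reads in the same order. The 3 footprint libraries with under 5e+05 reads were all WT, namely the cytosol libraries b of 0.5 h (298970) and 1 h (388975) and the ER library b of 1 h (418199). The 5 mRNA libraries with under 20000 reads were S51A cytosol 0 h b (14122), S51A ER 1 h b (9647) and 2 h b (667), and those labelled ATF4-/- of cytosol 0 h (1692) and ER 1 h (207). Below, a log2 change is given ± its standard error over 2 libraries per group in each of 2 fractions, counted as separate samples although they come from the same cells, and a level in RPKM ± SD with n = 2.

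The targeted genes were examined first. Atf4 (chromosome 15, 80255184 to 80257541 on GRCm38, 3 exons, a coding length of 1050 nt and a 5′ UTR of 594 nt) was not silent in the libraries labelled ATF4-/-. In their cytosol fraction its footprint level was 7.45 ± 0.759 RPKM untreated and 122 ± 34.9, 194 ± 71.3, 223 ± 80.6 and 223 ± 85.8 RPKM at 0.5, 1, 2 and 4 h. In the ER fraction it was 4.09 ± 1.80 untreated, then 44.4 ± 3.96, 86.7 ± 36.6, 118 ± 49.3 and 139 ± 41.0 RPKM. In WT cytosol the levels were 87.1 ± 18.9, 658 ± 135, 836 ± 5.85, 908 ± 12.9 and 782 ± 2.28 RPKM from 0 to 4 h. WT ER had 44.5 ± 18.1, 373 ± 7.50, 389 ± 53.7, 652 ± 14.04 and 588 ± 5.08 RPKM. S51A cytosol had 28.8 ± 8.54, 50.8 ± 28.5, 36.9 ± 4.24, 35.1 ± 12.1 and 46.2 ± 14.9 RPKM. S51A ER had 15.9 ± 10.4, 8.37 ± 2.30, 14.6 ± 6.19, 14.4 ± 0.5996 and 19.4 ± 5.10 RPKM. The authors' pooled Atf4 mRNA total in the libraries labelled ATF4-/- was 10.5 RPKM untreated and 51.7 and 139 RPKM at 1 and 4 h. Which part of the allele was removed is not given in the sources used here, so the Atf4 reads neither support nor contradict a loss of the protein. The S51A substitution changes a codon of Eif2s1, the gene of eIF2α, and the level of Eif2s1 checks nothing. Its pooled footprint totals were 409, 376 and 475 RPKM at 0, 1 and 4 h in WT and 115, 146 and 196 RPKM in S51A. In libraries labelled ATF4-/- they were 274, 218 and 225 RPKM.

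RPKM levels are relative, so no global fall of translation can show. At 1 h in WT, footprints of the PERK effectors rose steeply. Ddit3, which encodes the stress transcription factor CHOP (chromosome 10, 127290829 to 127293753, 4 exons), rose by 4.53 ± 0.32 log2 (adjusted p = 2.0e-12). Ppp1r15a, the phosphatase subunit that reverses eIF2α phosphorylation (chromosome 7, 45522916 to 45526268, 3 exons), rose by 3.98 ± 0.19 (8.9e-17) and Atf4 by 3.21 ± 0.30 (1.0e-09). Rcan1, a calcineurin regulator, rose by 4.83 ± 0.34 (2.0e-12), and Gadd45a, a growth arrest gene, by 2.19 ± 0.29 (9.4e-07). Of 16 measured mRNAs with upstream open reading frames reported to resist eIF2α phosphorylation, 7 rose and none fell (7 adjusted over the list alone). The list median was 0.57 and the camera adjusted p 1.1e-06, or 0.023 with an estimated correlation. Asns (−0.42 ± 0.20, adjusted p = 0.12), asparagine synthetase, and Trib3 (0.65 ± 0.30, 0.11), a pseudokinase induced by CHOP, did not pass. Neither did the housekeeping genes Gapdh (−0.05, 0.90) and Actb (−0.14, 0.62).

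Other groups moved in WT by 1 h. Of 20 measured ATF4-CHOP stress effectors 9 rose and 2 fell (9 and 2 adjusted over the list alone). The adjusted p was 2.7e-05, and adjusted p = 0.17 with an estimated correlation. Of 30 immediate early genes 19 rose and 2 fell (20 and 2 over the list alone). Klf10, a TGF-β response gene, rose by 2.26 ± 0.16 log2, Zfp36, which destabilises cytokine mRNAs, by 2.03 ± 0.22 and Junb, an AP-1 subunit, by 1.98 ± 0.23. The list's adjusted p was 5.4e-11, and adjusted p = 0.062 with an estimated correlation. NF-κB and cytokine genes had 12 of 21 higher and 1 lower (13 and 1 over the list alone). Nfkbia, the NF-κB inhibitor, rose by 1.87 ± 0.21, Irf1, an interferon regulatory factor, by 1.62 ± 0.20, and Ptgs2, the inducible prostaglandin synthase, by 2.95 ± 0.41. This list passed in both forms (adjusted p = 9.0e-09, and 0.013 with an estimated correlation).

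Footprints of several abundant housekeeping genes fell at 1 h in WT. They included Pabpc1, the poly(A)-binding protein (−1.69 ± 0.34, adjusted p = 3.7e-04), the ribosomal protein genes Rpl12 (−1.16 ± 0.22, 2.3e-04) and Rps7 (−0.94 ± 0.16, 5.1e-05), and Ldha, lactate dehydrogenase (−0.84 ± 0.15, 7.2e-05). Tuba1b, an α-tubulin (−0.92 ± 0.19, 4.5e-04), the mitotic cyclin Ccnb2 (−0.88 ± 0.17, 3.0e-04) and Ccng1, a p53 target (−1.38 ± 0.20, 3.8e-06), also fell. The largest falls by the naming rule, Dclk1 (−3.69 ± 0.53) and Eif4ebp2 (−3.43 ± 0.54), were of genes under the depth filter. None of these groups passed as a list: 13 of 80 ribosomal protein genes fell and 4 rose (adjusted p = 0.27). Likewise 5 of 15 translation factors with 5′ TOP mRNAs fell and 1 rose (0.31). Glycolysis had 7 of 16 lower and 1 higher (0.11), and mitotic genes 7 of 21 lower (0.31). Of the others, nuclear-encoded oxidative phosphorylation had 9 of 43 lower and 4 higher (0.62), and Nrf2 targets 4 of 17 lower (0.19). Autophagy and lysosome (1 higher and 5 lower of 24), S phase (3 and 3 of 22), and cytoskeleton (5 and 5 of 28) did not pass. Nor did aminoacyl-tRNA synthetases (3 and 2 of 19), heat shock proteins (2 and 2 of 17), p53 targets (3 and 2 of 15) or amino acid genes (2 and 0 of 24).

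In all, 3006 of 10419 genes passed in WT at 1 h, 1289 higher and 1717 lower. Among the 2779 genes with at least 20 predicted reads in every compared library it was 1147, 458 higher and 689 lower. The split was 1519 higher and 1476 lower under TMM-type scaling, and 1380 and 946 with voom. It was 1548 and 1467 without the shallow libraries, where 1987 of the 3006 were called again and 28 had the other sign. In simulation 63.1% of calls were unchanged genes, 12.2% with the depth filter.

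ER-targeted genes need their fractions set apart at 1 h, since the averaged change also moves when footprints pass from one fraction to the other. Hspa5, the ER chaperone BiP, rose by 1.98 ± 0.43 log2 on average (adjusted p = 8.5e-04) and by 3.41 ± 0.61 in the cytosol fraction (1.2e-04), and stood at 0.55 ± 0.61 in the ER fraction (0.56). The authors' pooled Hspa5 total went from 719 to 1153 RPKM. Calr, the chaperone calreticulin, rose by 3.84 ± 0.57 in cytosol (9.7e-06) and stood at −0.20 ± 0.57 in ER (0.85). Herpud1 (chromosome 8, 94386438 to 94395377, 8 exons), which serves ER-associated degradation, rose in both, by 2.97 ± 0.30 and 2.00 ± 0.30 (1.7e-08 and 2.1e-05). On the averaged scale 11 of 30 ER chaperones rose and 1 fell (13 and 1 over the list alone; adjusted p = 0.0012, and adjusted p = 0.91 with an estimated correlation). Of 35 integral plasma membrane proteins 9 rose (9 over the list alone; 0.0099, and adjusted p = 0.98 with an estimated correlation). Of 2400 ER-targeted genes 350 rose and 145 fell (317 and 126; 0.0080, and adjusted p = 0.98). Lists of ER-associated degradation (5 higher and 3 lower of 20), ER-Golgi transport (12 and 5 of 37), extracellular matrix (9 and 1 of 53), cholesterol synthesis (1 and 1 of 24) and reported RIDD substrates (3 and 0 of 10), mRNAs cut by IRE1, did not pass.

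At 4 h the question was which programme had followed in WT. CHOP and ATF4 targets now rose with their regulators. Ddit3 was up by 4.57 ± 0.32 log2 (adjusted p = 1.5e-12), Atf4 by 3.46 ± 0.30 (2.7e-10), and Trib3 by 2.83 ± 0.30 (2.7e-08). Atf3, a stress transcription factor, rose by 3.0 ± 0.34 (8.1e-08) and Asns (chromosome 6, 7675169 to 7693254, 12 exons) by 0.97 ± 0.20 (7.2e-04). Of 20 ATF4-CHOP effectors 11 rose (15 adjusted over the list alone; list adjusted p = 5.9e-13, and 0.011 with an estimated correlation). Of 19 aminoacyl-tRNA synthetases, which charge tRNAs, 13 rose (14 over the list alone; 2.9e-09, and 0.042), led by Tars at 1.13 ± 0.12 and Sars at 0.90 ± 0.11. Amino acid synthesis and transport genes had 14 of 24 higher (16 over the list alone; 8.3e-09, and adjusted p = 0.22 with an estimated correlation). Got1, aspartate aminotransferase, rose by 1.22 ± 0.14 and Slc3a2, an amino acid carrier subunit, by 1.95 ± 0.31. Of the upstream reading frame mRNAs 8 of 16 rose (8 over the list alone; 6.1e-08, and 0.015), among them Ibtk at 1.91 ± 0.16.

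ER folding genes also rose at 4 h in WT. Sdf2l1, a cofactor of BiP (chromosome 16, 17130138 to 17132383, 3 exons), rose by 3.18 ± 0.34 (3.0e-08), Manf, a secreted ER stress protein, by 2.45 ± 0.34 (3.1e-06) and Herpud1 by 3.47 ± 0.21 (4.1e-14). Hspa5 rose by 1.97 ± 0.43 on average (1.3e-03) and by 2.42 ± 0.61 in the ER fraction (0.0099), and its pooled total reached 3817 RPKM. Of 30 ER chaperones 10 rose (13 over the list alone; 3.3e-05, and adjusted p = 0.79 with an estimated correlation). ER-Golgi transport had 15 of 37 higher (18 over the list alone; 4.0e-04, and adjusted p = 0.60) and ER-associated degradation 7 of 20 (7; 0.0073, and adjusted p = 0.81). NF-κB and cytokine genes had 9 higher and 1 lower of 21 (12 and 2; 0.0035, and adjusted p = 0.27), with Cxcl10, a chemokine, at 2.79 ± 0.42.

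Growth and cytoskeletal genes fell at 4 h in WT. Of 28 cytoskeleton genes 14 fell (15 over the list alone; 2.2e-09, and 0.035 with an estimated correlation). Tubb4b, a β-tubulin, was at −1.54 ± 0.17, Actg1, γ-actin, at −1.33 ± 0.19 and Actb, β-actin, at −0.92 ± 0.18. Mitotic genes had 9 of 21 lower (13 over the list alone; 3.6e-09, and adjusted p = 0.17), with the kinases Cdk1 at −0.88 ± 0.12 and Plk1 at −1.11 ± 0.18. Glycolysis had 10 of 16 lower and 2 higher (10 and 2; 6.5e-06, and adjusted p = 0.17), with Pgam1 at −0.71 ± 0.13. Of 8 muscle and myofibroblast markers, several of them actins that fibroblasts also make, 4 fell (5; 6.4e-04, and adjusted p = 0.068). Extracellular matrix (2 of 53 lower, 0 over the list alone; 6.8e-04, and adjusted p = 0.97) passed with the preset correlation alone. So did oxidative phosphorylation (4 of 43 lower, 3 over the list alone; 0.0038, and adjusted p = 0.54) and ribosomal proteins (4 of 80 lower, 1 over the list alone; 0.012, and adjusted p = 0.96). The calcium-binding S100a4 stood at −2.63 ± 0.45 and the EGFR inhibitor Errfi1 at −2.26 ± 0.21. Bloc1s1, the best-known RIDD substrate, fell by 1.13 ± 0.20 (8.1e-05), and 2 of 10 listed substrates fell (0.15). Immediate early genes were mixed, 8 higher and 4 lower of 30 (0.93). Of the remaining lists, autophagy (4 higher and 1 lower), cholesterol (3 and 0), heat shock (1 and 2), and plasma membrane (1 and 2) did not pass. Neither did Nrf2 (3 and 4), p53 (1 and 2), S phase (5 and 3), TOP factors (1 and 0) or ER-targeted genes (203 and 61 of 2401). Fibroblast (0 and 1 of 14), endothelial (0 and 0 of 3) and neural markers (1 and 0 of 5) did not pass either. In all 1836 genes passed, 1298 higher and 538 lower. The libraries at 1 h and 4 h were set against the same untreated libraries of their genotype, so counts at the 2 times share chance values.

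**Figure D1:**
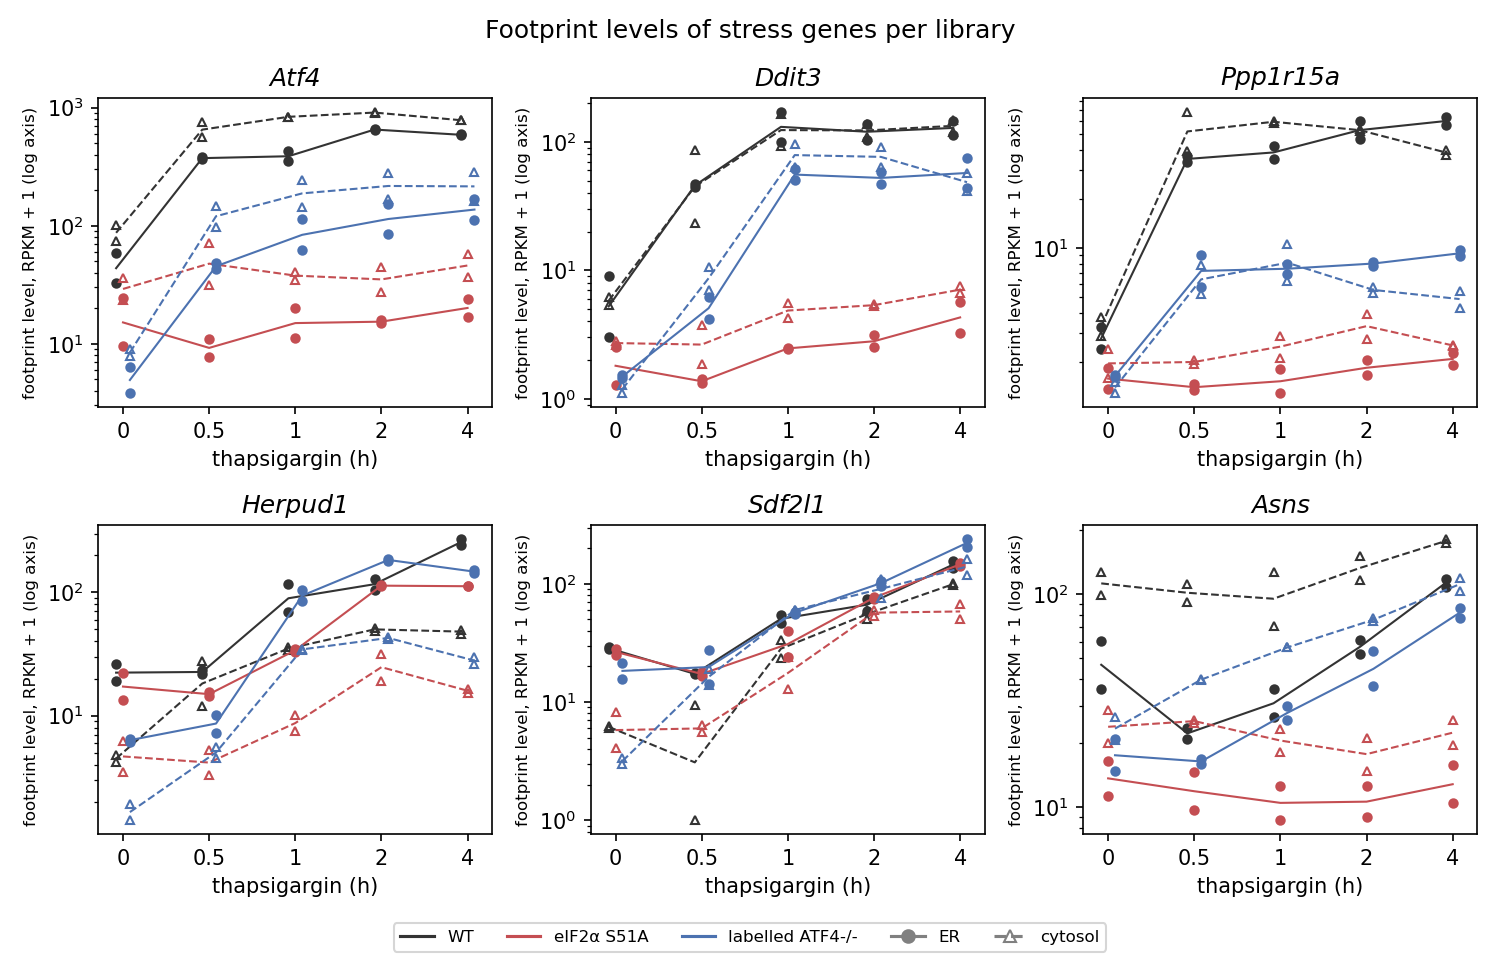
Footprint levels (RPKM + 1, log axis) of Atf4, Ddit3, Ppp1r15a, Herpud1, Sdf2l1 and Asns against hours of thapsigargin, 1 symbol per library and lines through the means of the log values, with times spaced evenly and ER as filled circles and cytosol as open triangles, for WT, S51A and libraries labelled ATF4-/-. Atf4 in WT cytosol went from 87.1 to 836 RPKM at 1 h, against 28.8 to 36.9 RPKM in S51A and 7.45 to 194 RPKM in libraries labelled ATF4-/-.

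S51A cells test what remains when eIF2α cannot be phosphorylated. At 1 h little had changed: Atf4 was at 0.18 ± 0.30 log2, Ddit3 at 0.64 ± 0.32, Ppp1r15a at 0.14 ± 0.19 and Hspa5 at 0.17 ± 0.43. None of them passed. Rcan1 rose by 3.51 ± 0.34 (adjusted p = 7.1e-09), Klf10 by 2.00 ± 0.16 (3.3e-10), the AP-1 subunit Fosl1 by 1.81 ± 0.24 (1.5e-05). Chac1, a glutathione-degrading enzyme, rose by 1.25 ± 0.21 (7.0e-04) and Herpud1 by 0.94 ± 0.21 (0.029). Immediate early genes went both ways, 5 higher and 8 lower of 30 (10 and 11 adjusted over the list alone), with a list median of −0.04 (adjusted p = 0.66). Besides Klf10 and Fosl1, which rose, Fos was at −3.28 ± 0.29, Ier2 at −2.81 ± 0.26, Zfp36 at −2.50 ± 0.22 and Egr1 at −2.30 ± 0.20. In all 39 of 10417 genes passed, 20 higher and 19 lower, and with TMM-type scaling 27 were higher and 14 lower. The count was 25 without ER 0 h library b, 21 without cytosol 1 h a, and 20 without ER 1 h a or cytosol 0 h a. Cytosolic heat shock proteins lay above other genes as a list (median 0.22, adjusted p = 1.0e-07, and 0.016 with an estimated correlation) with no member called, 4 over the list alone. Cytoskeleton genes did so too (3.6e-04, 0 called and 1 over the list alone, and adjusted p = 0.33 with an estimated correlation). Plasma membrane proteins (median −0.43, 5.6e-05, and adjusted p = 0.91) and extracellular matrix (−0.40, 7.9e-05, and adjusted p = 0.94) lay below other genes with no member called.

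By 4 h ER folding genes rose in S51A. Sdf2l1 rose by 2.90 ± 0.34 log2 (adjusted p = 2.4e-07) and Manf by 2.07 ± 0.34 (8.4e-05). Creld2, an ER protein of the same response, rose by 2.54 ± 0.44 (1.7e-04), Herpud1 by 2.24 ± 0.21 (1.3e-09) and Edem1, an ER-associated degradation factor, by 1.51 ± 0.24 (4.2e-05). Hspa5 went from 754 to 3694 RPKM in the authors' totals. Of 27 ER chaperones 9 rose (9 over the list alone; 1.0e-04, and adjusted p = 0.84 with an estimated correlation). Of 20 degradation genes 4 rose (5; 1.2e-04, and adjusted p = 0.54) and of 37 transport genes 6 (13; 8.0e-07, and adjusted p = 0.30). Ddit3 rose by 1.32 ± 0.32 (0.0065). Atf4 (0.53 ± 0.30, 0.33), Ppp1r15a (0.38, 0.27), Trib3 (0.13, 0.89) and Asns (−0.09, 0.88) did not pass. ATF4-CHOP effectors had 1 higher and 5 lower of 20 (1 and 5; 0.16) and amino acid genes 1 and 1 of 24 (0.62). The same counts were, for tRNA synthetases, 1 and 0 of 19 (0.92) and, for upstream reading frame mRNAs, 3 and 1 of 16 (0.48).

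Immediate early genes were the most lowered group in S51A at 4 h. Of 30, 18 fell and 1 rose (18 and 1 over the list alone). The list median was −1.85 and the adjusted p 5.0e-36, or 0.0010 with an estimated correlation. Fos, an AP-1 subunit (chromosome 12, 85473890 to 85477273, 4 exons), stood at −6.32 ± 0.29 and Egr1, a growth factor response gene (chromosome 18, 34859823 to 34864984, 3 exons), at −5.71 ± 0.20. Untreated Fos in cytosol was 270 ± 102 RPKM in S51A, 0.385 ± 0.545 in WT and 10.0 ± 0.194 in libraries labelled ATF4-/-. Atf3 fell by 3.98 ± 0.34. p53 targets had 6 of 15 lower (6 lower and 1 higher over the list alone; 4.3e-06, and 0.023 with an estimated correlation). Btg2, an antiproliferative gene that is also an early response gene, led them at −4.34 ± 0.29. NF-κB genes had 5 of 21 lower (5; 0.0040, and adjusted p = 0.29), extracellular matrix 7 of 51 (8; 0.0018, and adjusted p = 0.98) and mitotic genes 4 of 21 (5; 0.0023, and adjusted p = 0.75). In contrast, cytoskeleton genes had 5 higher and 1 lower of 26 (7 and 1; 0.0073, and adjusted p = 0.60). In all 857 of 10413 genes passed, 448 higher and 409 lower. The count was 420 without cytosol 4 h library a, 435 without ER 4 h a and 487 without cytosol 0 h a.

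**Figure D2:**
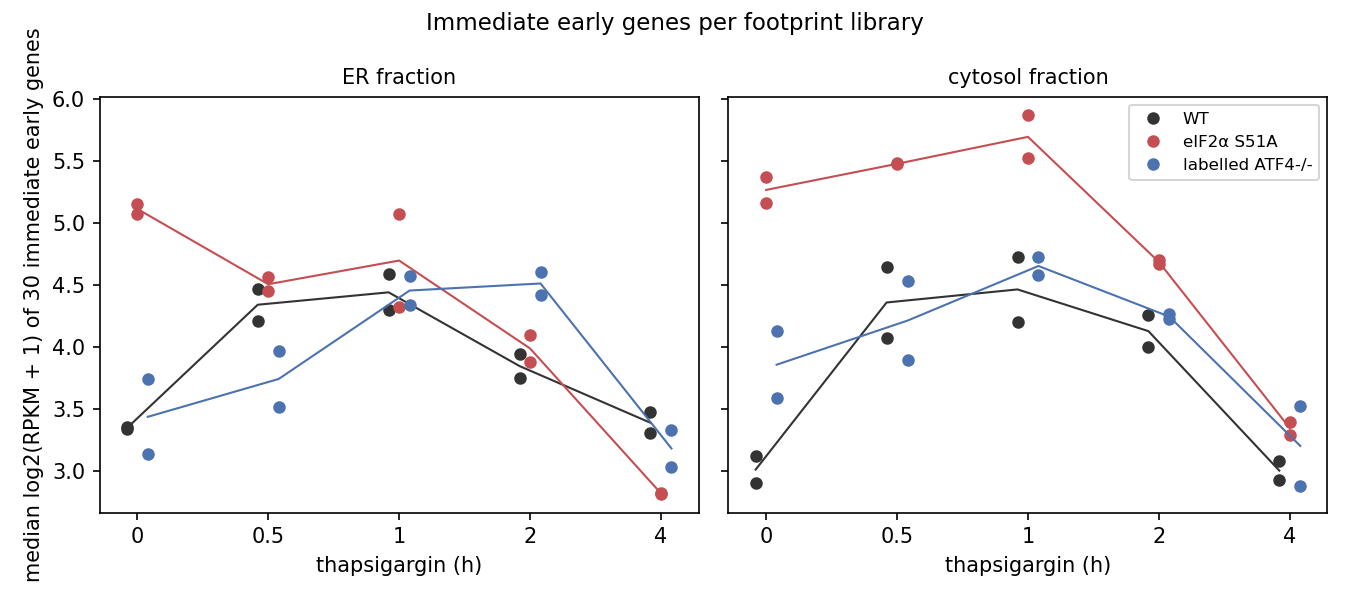
Median footprint level, log2(RPKM + 1), of 30 immediate early genes in each library against hours of thapsigargin, for WT, S51A and libraries labelled ATF4-/-, by fraction, with 1 symbol per library and lines through the means. In S51A the median change against untreated was −0.17 at 0.5 h and −1.85 at 4 h, against 0.77 and −0.05 in WT.

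Libraries labelled ATF4-/- answer what the response looks like with ATF4 impaired, as far as the label holds. Their stress genes rose at 1 h: Ddit3 by 5.63 ± 0.32 log2 (adjusted p = 2.7e-15), Atf4 by 4.28 ± 0.30 (7.8e-13), and Herpud1 by 4.14 ± 0.21 (3.3e-16). Chac1 rose by 3.56 ± 0.21 (6.8e-15), Ppp1r15a by 2.37 ± 0.19 (8.1e-11), Trib3 by 2.06 ± 0.30 (1.1e-05) and Asns by 0.96 ± 0.20 (1.1e-03). Of 20 ATF4-CHOP effectors 9 rose (9 adjusted over the list alone; 5.4e-10, and 0.017 with an estimated correlation) and of 16 upstream reading frame mRNAs 8 (8; 9.3e-09, and 0.012). Immediate early genes had 19 of 30 higher (20; 7.5e-17, and 0.016), with Fosb, an AP-1 subunit, at 2.81 ± 0.34. NF-κB genes had 9 of 21 higher (12; 5.5e-10, and 0.0096), with the chemokine Cxcl1 at 3.69 ± 0.50.

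Lipid, transport and ribosomal genes also moved at 1 h in the libraries labelled ATF4-/-. Of 24 cholesterol synthesis genes 9 rose (16 over the list alone; 7.5e-09, and adjusted p = 0.24 with an estimated correlation). Sc4mol, a sterol oxidase, was at 2.20 ± 0.31 log2, Insig1, the sterol sensor, at 1.68 ± 0.35 and Hsd17b7 at 1.14 ± 0.18. These are mostly ER membrane enzymes, for which passage between fractions enters the averaged change. ER-Golgi transport had 14 higher and 1 lower of 37 (20 and 3; 2.4e-05, and adjusted p = 0.46) and chaperones 9 of 30 higher (11; 5.8e-04, and adjusted p = 0.88). Of 80 ribosomal protein genes 15 fell and 6 rose (19 and 7; 8.5e-05, and adjusted p = 0.76), with Rpl17 at −1.21 ± 0.19 and Rps18 at −1.21 ± 0.21. Of 14 TOP factors 4 fell (5; 2.3e-04, and adjusted p = 0.24), with the elongation factor Eef1b2 at −1.03 ± 0.19. In all 1289 of 10418 genes passed, 729 higher and 560 lower. The count was 824 without cytosol 1 h library b, 836 without ER 1 h b and 839 without cytosol 0 h a.

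At 4 h the targets of ATF4 rose in the libraries labelled ATF4-/-. Trib3 rose by 4.73 ± 0.30 log2 (adjusted p = 7.3e-14), Asns by 2.24 ± 0.20 (4.5e-10), and Aldh1l2, a mitochondrial folate enzyme, by 2.93 ± 0.25 (1.3e-10). The aminotransferase gene Gpt2 rose by 2.24 ± 0.18 (3.5e-11) and Chac1 by 3.25 ± 0.21 (7.3e-14). Amino acid genes had 16 of 24 higher (19 over the list alone; 1.6e-14, and adjusted p = 0.057 with an estimated correlation), and ATF4-CHOP effectors 10 of 20 (11; 1.7e-12, and 0.012). Aminoacyl-tRNA synthetases had 13 of 19 higher with 1 lower (14 and 2; 1.0e-09, and 0.035) and upstream reading frame mRNAs 8 of 16 (10; 5.5e-11, and 0.0045). Untreated Asns stood at 22.6 ± 4.25 RPKM in the cytosol of these libraries against 113 ± 19.7 RPKM in WT cytosol, and reached 111 ± 11.4 against 177 ± 5.08 RPKM at 4 h.

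The folding genes rose strongly as well. Sdf2l1 rose by 4.53 ± 0.34 (8.2e-12), Herpud1 by 4.31 ± 0.21 (9.1e-17), Manf by 3.95 ± 0.34 (1.6e-10) and the ER chaperone Hsp90b1 by 1.94 ± 0.42 (1.3e-03). The authors' Hspa5 total went from 414 to 5448 RPKM. Of 29 chaperones 14 rose (19 over the list alone; 8.4e-09, and adjusted p = 0.54 with an estimated correlation), of 37 transport genes 23 (27; 3.2e-13, and adjusted p = 0.057). Degradation genes had 9 of 20 higher with 1 lower (9 and 1; 7.7e-04, and adjusted p = 0.65), and of 24 cholesterol genes 6 (9; 0.0054, and adjusted p = 0.85). NF-κB genes had 6 of 21 higher (6; 0.035, and adjusted p = 0.55) and ER-targeted genes 249 higher and 26 lower of 2399 (223 and 24; 0.015, and adjusted p = 0.98). Falls were seen in immediate early genes, 9 of 30 with 3 higher (9 and 5; 0.0033, and adjusted p = 0.69), with Egr1 at −3.64 ± 0.20. They were also seen in mitotic genes, 8 of 21 (8; 4.2e-05, and adjusted p = 0.52), and in heat shock proteins, 3 of 17 (6; 5.1e-04, and adjusted p = 0.17). In all 1643 of 10418 genes passed, 1003 higher and 640 lower. Of the genes called in WT, libraries labelled ATF4-/- shared 472 of the higher and 373 of the lower at 1 h, where independent lists would share 90.1 and 92.3. At 4 h it was 494 and 193, where they would share 125 and 33.1. For S51A 12 higher and 0 lower were shared with WT at 1 h, with 2.48 and 3.13 for independent lists. At 4 h it was 190 and 53, with 55.8 and 21.1. Of the genes called higher and lower in WT, 7 and 0 at 1 h and 45 and 20 at 4 h were called the other way in S51A. Genes higher in WT at 1 h had a median of −0.06 in S51A, where 40.3% had the same sign. Each genotype had its own untreated libraries in these overlaps.

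**Figure D3:**
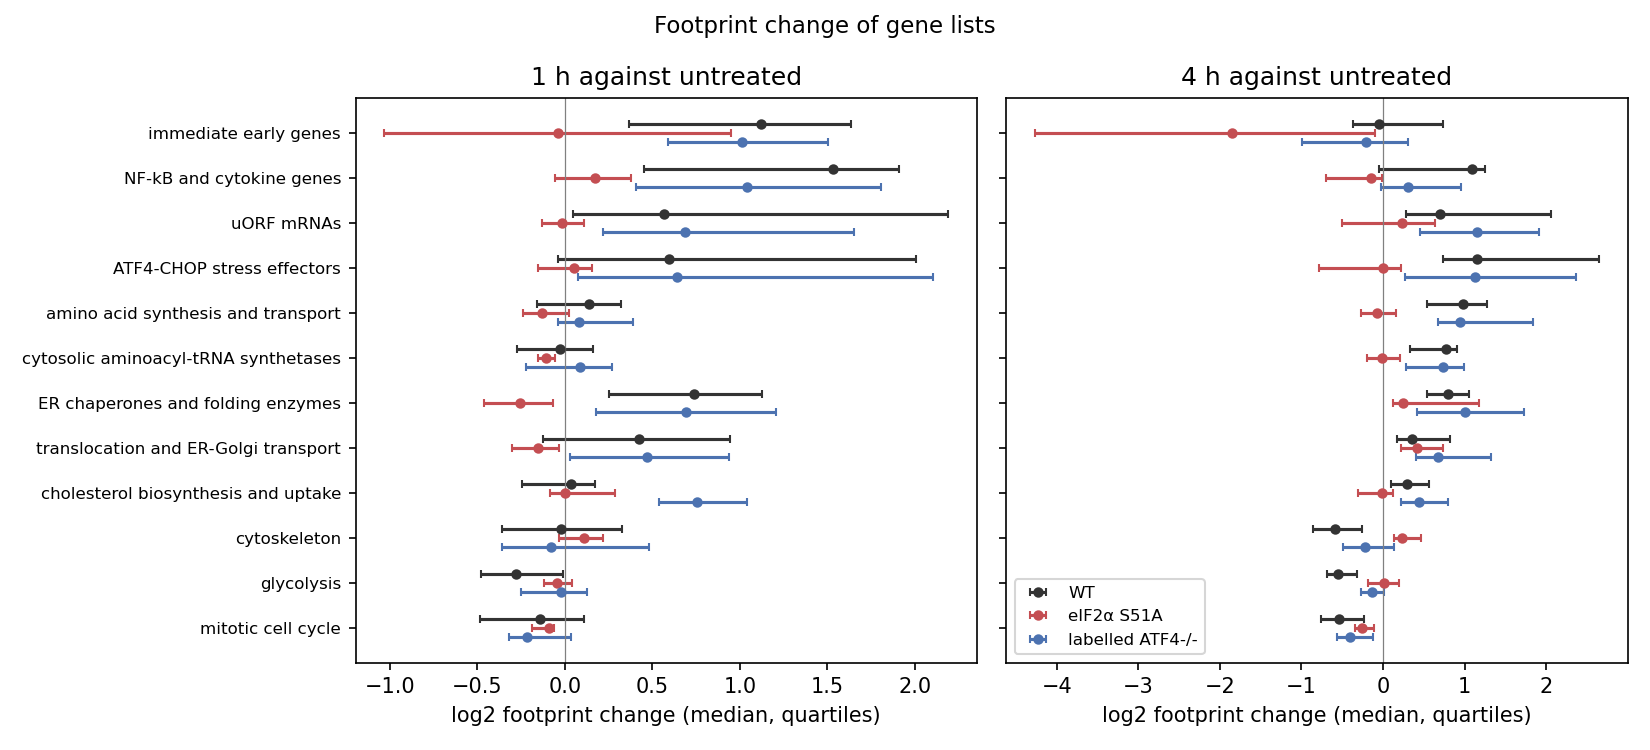
Median log2 footprint change against untreated, with quartiles as bars, of 12 gene lists at 1 h and 4 h in WT, S51A and libraries labelled ATF4-/-, as the mean of both fractions, with a separate scale for each time. At 4 h the ATF4-CHOP list lay at 1.16 in WT, 0.00 in S51A and 1.12 in libraries labelled ATF4-/-, and the immediate early list at −0.05, −1.85 and −0.21.

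Whether the genotypes differed from WT was tested by the difference of their changes, in which both genotypes share the WT libraries. In S51A at 1 h the change of the PERK effectors was lower than in WT, by −3.84 ± 0.28 log2 for Ppp1r15a (adjusted p = 5.7e-12), −3.88 ± 0.45 for Ddit3 (4.2e-07) and −3.03 ± 0.42 for Atf4 (1.0e-05). Fos (−4.90 ± 0.41) and Zfp36 (−4.53 ± 0.31), which fell in S51A, and Nfkbia (−2.45 ± 0.29, 6.4e-07) also had a lower change than in WT. So did the tetraspanin Cd9 (−2.24 ± 0.39, 3.2e-04), for which passage between fractions in WT enters the difference. Odc1, ornithine decarboxylase, differed by 2.28 ± 0.40 (3.0e-04). At 4 h the differences were −3.60 ± 0.28 for Ppp1r15a, −3.25 ± 0.45 for Ddit3 and −2.93 ± 0.42 for Atf4. They were −2.70 ± 0.43 for Trib3, −1.06 ± 0.29 for Asns (0.015) and −1.24 ± 0.16 for Sars (1.4e-06). Atf3, which fell in S51A, differed by −6.98 ± 0.48. Sdf2l1 (−0.28 ± 0.49, 0.82) and Dnajb9, an ER cochaperone (−1.16 ± 0.59, 0.26), did not pass. Tubb4b (1.68 ± 0.25) and Cdk1 (0.83 ± 0.17) differed the other way.

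The differences for S51A numbered 1142 of 10415 genes at 1 h, 500 higher and 642 lower, and 833 of 10413 at 4 h, 269 higher and 564 lower. The count at 1 h was 607 among genes with at least 20 predicted reads (323 higher, 284 lower) and 1727 without WT cytosol 1 h library a (953 and 774), so more were then higher. It was 735 without S51A cytosol 0 h b and 738 without WT ER 0 h b.

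For libraries labelled ATF4-/- few differences from WT passed, 69 at 1 h (45 higher, 24 lower) and 204 at 4 h (58 higher, 146 lower). Atf4 (1.07 ± 0.42 log2, adjusted p = 0.21, and 1.27 ± 0.42, 0.11) and Ddit3 at 1 h (1.11 ± 0.45, 0.23) did not differ past the threshold. Ppp1r15a rose less, by −1.61 ± 0.28 at 1 h (2.8e-03) and −1.83 ± 0.28 at 4 h (1.7e-04), as did Rcan1 at 1 h (−3.14 ± 0.48, 5.3e-04). Fos, which fell at 4 h in these libraries, differed by −2.83 ± 0.41 (1.7e-04). The change of Asns was higher at both times (1.39 ± 0.29 and 1.27 ± 0.29, both 0.013), as was that of Trib3 (1.90 ± 0.43, 0.013) and Aldh1l2 (1.67 ± 0.35) at 4 h. With TMM-type scaling 43 were higher and 49 lower at 1 h. The count at 1 h depended on single libraries. It was 712, 104, 40, 544, 170 and 33 without WT cytosol 1 h a, cytosol 1 h b, cytosol 0 h a, ER 1 h a, ER 0 h a and ER 0 h b. It was 41, 27, 40, 37 and 34 without the libraries labelled ATF4-/- of cytosol 1 h b, ER 1 h b, cytosol 0 h a, cytosol 0 h b and ER 0 h b. At 4 h it was 118, 115 and 132 without WT cytosol 4 h b, cytosol 0 h b and ER 0 h a, while it was 132, 126, 104 and 121 without those labelled ATF4-/- of cytosol 4 h b, ER 4 h a, cytosol 0 h a and ER 0 h b.

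The mRNA of WT cells was tested to see which changes lay in transcript level, at a depth where the simulation without the depth filter called no change. At 4 h 7 of 10600 genes passed, all higher, among them Cth, the cystathionine lyase (3.73 ± 0.53 log2, adjusted p = 5.5e-04), and Chac1 (3.12 ± 0.61, 0.040). Hspa5 mRNA was at 2.19 ± 0.54 (0.19) and Atf4 mRNA at 1.75 ± 0.95, neither past the threshold. ER chaperones as a list had a median of 1.13 (2.1e-07, 0 called and 2 over the list alone, and adjusted p = 0.20 with an estimated correlation), and amino acid genes 0.90 (3.8e-06, 1 of 21 higher, and 0.013). ATF4-CHOP effectors had 1 of 19 higher (4 over the list alone; 0.028, and adjusted p = 0.41), and cytoskeleton and ribosomal proteins passed below other genes with none called (0.0031 and 0.0040, and adjusted p = 0.88 and 0.94). The count was 2 without cytosol 4 h library a or b, 4 without ER 4 h b, and 3 without cytosol 0 h a, ER 0 h a or ER 0 h b. With a pseudocount of 0.25 it was 2. At 1 h limma called 0 genes, 264 had an unadjusted p under 0.05, and voom called 0. The count was 1 without cytosol 1 h b. Chaperones (median 0.74, 2.1e-05, and adjusted p = 0.35) and NF-κB genes (1.019, 1.7e-05, and adjusted p = 0.052) lay above other genes as lists at 1 h, and neural markers below (−1.22, 0.0054, and adjusted p = 0.17).

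Translational efficiency, the footprint change beyond the mRNA change, rose at 1 h in WT for Ddit3 (3.85 ± 0.72 log2, adjusted p = 4.6e-03), Ppp1r15a (3.51 ± 0.59, 1.5e-03) and Atf5, a relative of ATF4 (4.65 ± 0.88, 4.6e-03). Atf4 stood at 2.01 ± 0.91 (0.74). Upstream reading frame mRNAs had 3 of 15 higher (3 over the list alone; 8.0e-08, and adjusted p = 0.074 with an estimated correlation) and ATF4-CHOP effectors 3 of 19 (4; 9.8e-04, and adjusted p = 0.16). Immediate early genes (0 called, 1 over the list alone; 2.0e-05, and adjusted p = 0.18) and 5 neural markers (0 called, 3 over the list alone; 4.7e-04, and 0.030) passed as lists. In simulation 2 of 4 calls at 1 h and 3 of 5 at 4 h were unchanged genes. In all 6 genes passed at 1 h, 4 higher and 2 lower (12 and 17 under TMM-type scaling). The count was 1 without ER footprint 1 h library b, 12 without ER footprint 1 h a, 14 without cytosol footprint 1 h a, 12 without cytosol mRNA 1 h a, and 11 without ER mRNA 1 h a or ER mRNA 0 h a. At 4 h limma called 0, 435 had an unadjusted p under 0.05, and voom called 0. There the count was 3 without ER mRNA 4 h a and 1 without cytosol mRNA 4 h a or cytosol mRNA 0 h b. ATF4-CHOP effectors still passed as a list (median 1.00, 0 called and 1 over the list alone; 1.3e-05, and 0.030).

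mRNA in S51A rests on libraries of very unequal depth. Its untreated cytosol library b, a baseline of every S51A mRNA comparison, stood apart, with reads on 956 genes only and Samd1 as its top gene. The chi-square per degree of freedom of that pair of libraries was 52.5 and the SD of their log2 ratios 4.34, the highest of the 20 mRNA pairs. Untreated S51A cells had more mRNA than untreated WT cells for Junb (6.34 ± 0.78 log2, adjusted p = 1.6e-05), Fos (4.40 ± 0.97, 6.8e-03), the collagen Col1a1 (5.04 ± 0.84, 4.8e-04) and the ribosomal protein Rps26 (4.06 ± 0.48, 8.5e-06), and less for Cxcl5, a chemokine (−7.29 ± 0.64, 3.2e-08), and Ddit3 (−3.60 ± 0.72, 2.9e-03). Of 80 ribosomal protein genes 24 were higher and 1 lower (35 and 1 over the list alone; 1.7e-19, and adjusted p = 0.17 with an estimated correlation). Of 29 immediate early genes 4 were higher (9; 1.0e-05, and adjusted p = 0.18) and of 12 fibroblast markers 3 (3; 3.0e-04, and adjusted p = 0.24). Of 50 matrix genes 4 were higher and 1 lower (6 and 1; 3.6e-04, and adjusted p = 0.85). Epithelial (0 of 3, 0.98), macrophage (0 of 3, 0.61), neural (0 of 5, 0.53) and endothelial markers (0 of 4, 0.29) did not differ past the threshold. Muscle markers had 0 of 6 called (2 over the list alone; 0.040, and adjusted p = 0.54). In all 530 genes differed, 156 higher and 374 lower, and 67 higher and 1011 lower under TMM-type scaling, which moved the median of all genes from −0.21 to −1.05. The count was 919, 249 and 234 without S51A cytosol 0 h library a, ER 0 h a and ER 0 h b, and 204, 253, 247 and 254 without WT cytosol 0 h a, cytosol 0 h b, ER 0 h a and ER 0 h b.

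After thapsigargin, 7 mRNAs passed in S51A at 1 h (5 higher, 2 lower) and 6 at 4 h (3 and 3). Under TMM-type scaling it was 2 and 0, and 3 and 1. In simulation 4 of 7 calls at 1 h were unchanged genes. Ddit3 mRNA rose by 4.83 ± 0.72 log2 (adjusted p = 2.5e-03) and 4.43 ± 0.72 (5.6e-03), although it was listed at 0 in both untreated cytosol libraries, and Junb fell by 5.87 ± 0.78 at 4 h (2.9e-04). Junb alone differed from WT at 4 h (−6.62 ± 1.11, 0.018). The count at 1 h was 480 and 110 without cytosol 0 h library a and b, 15 without ER 1 h a, 4 without ER 0 h b, 2 without ER 0 h a and 1 without cytosol 1 h b. At 4 h it was 670 and 11 without cytosol 0 h a and b, 2 without ER 4 h a, and 3 without cytosol 4 h a, cytosol 4 h b, ER 4 h b, ER 0 h a or ER 0 h b. The single difference from WT became 102 without S51A cytosol 0 h a, and 2 without S51A cytosol 0 h b or WT ER 4 h b. It became 0 without S51A cytosol 4 h b, ER 4 h a or ER 0 h a, or WT cytosol 4 h b, ER 4 h a, cytosol 0 h a, cytosol 0 h b or ER 0 h a. At 4 h immediate early mRNAs had 2 of 29 lower (7 over the list alone; 1.8e-12, and 0.017 with an estimated correlation).

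Efficiency in S51A passed for 46 genes at 1 h (25 higher, 21 lower) and for 110 at 4 h (2 higher, 108 lower). At 1 h voom called 0 higher and 12 lower, and without the shallow libraries 638 were higher and 254 lower. At 4 h the median of all genes was −0.73 (−1.09 under TMM-type scaling), but 0.38 with voom, which called 8 higher and 9 lower and shared 2 of the 110. Ddit3 stood at −4.19 ± 0.72 log2 at 1 h (adjusted p = 2.0e-03) and −3.12 ± 0.72 at 4 h (0.020), and Uqcrb, a respiratory chain subunit, at −3.63 ± 0.52 at 4 h (2.4e-05). In simulation at 1 h 78.8% of calls were unchanged genes. With single libraries left out the count at 1 h was 769 (276 higher, 493 lower) and 521 (467 and 54) for cytosol mRNA 0 h a and b, 286 and 116 (ER mRNA 1 h a and b), and 126 (cytosol mRNA 1 h a). It was 22 and 20 (ER footprint 0 h a and b), 19 (cytosol footprint 1 h a), 22 and 30 (ER footprint 1 h a and b) and 20 (cytosol footprint 0 h a). At 4 h it was 1629 (cytosol mRNA 0 h a), 20 (ER mRNA 0 h b), and 36 and 50 (ER mRNA 4 h a and b). It was also 22 and 26 (ER footprint 0 h a and b), 8 and 31 (cytosol footprint 4 h a and b), 8 and 32 (ER footprint 4 h a and b) and 10 and 30 (cytosol footprint 0 h a and b).

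The last question was whether thapsigargin moved translation off the ER. In WT, the ER to cytosol footprint ratio fell for some secretory and membrane protein genes by 1 h. Cd9 (chromosome 6, 125460266 to 125494791, 8 exons) went in the cytosol fraction from 19.2 ± 3.09 to 339 ± 101 RPKM at 1 h and in the ER fraction from 732 ± 97.0 to 506 ± 131 RPKM. Its pooled total moved from 751 to 845 RPKM, and its share on the ER from 97.4% to 59.9%. The log2 ratio of ER to cytosol changed by −4.60 ± 0.56 for Cd9 (adjusted p = 2.2e-06), −5.15 ± 0.59 for the receptor Il1rl1 (6.9e-07), and −3.17 ± 0.34 for Sar1b, a GTPase of ER exit sites (chromosome 11, 51763687 to 51791925, 7 exons; 2.7e-07). Atf4 was at −0.11 and did not pass.

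Over the genes the authors call ER-targeted with a deposited value at each time (n = 1313), the median share of footprints on the ER in WT was 92.6% untreated, 47.3% at 0.5 h, 66.9% at 1 h, 73.7% at 2 h and 85.1% at 4 h. Over the other 7270 genes it was 39.1%, 34.03%, 38.6%, 40.5% and 43.9%. In S51A the ER-targeted genes (n = 2302) had 90.8%, 85.0%, 90.4%, 79.7% and 90.7%, and in libraries labelled ATF4-/- (n = 2110) 93.8%, 65.3%, 74.8%, 82.8% and 83.2%. These are the authors' pooled values. The 79.7% of S51A at 2 h stands beside a cytosol library b in which 11.6% of reads were of ER-targeted genes, and the WT cytosol library b of 0.5 h had 15.6%.

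**Figure D4:**
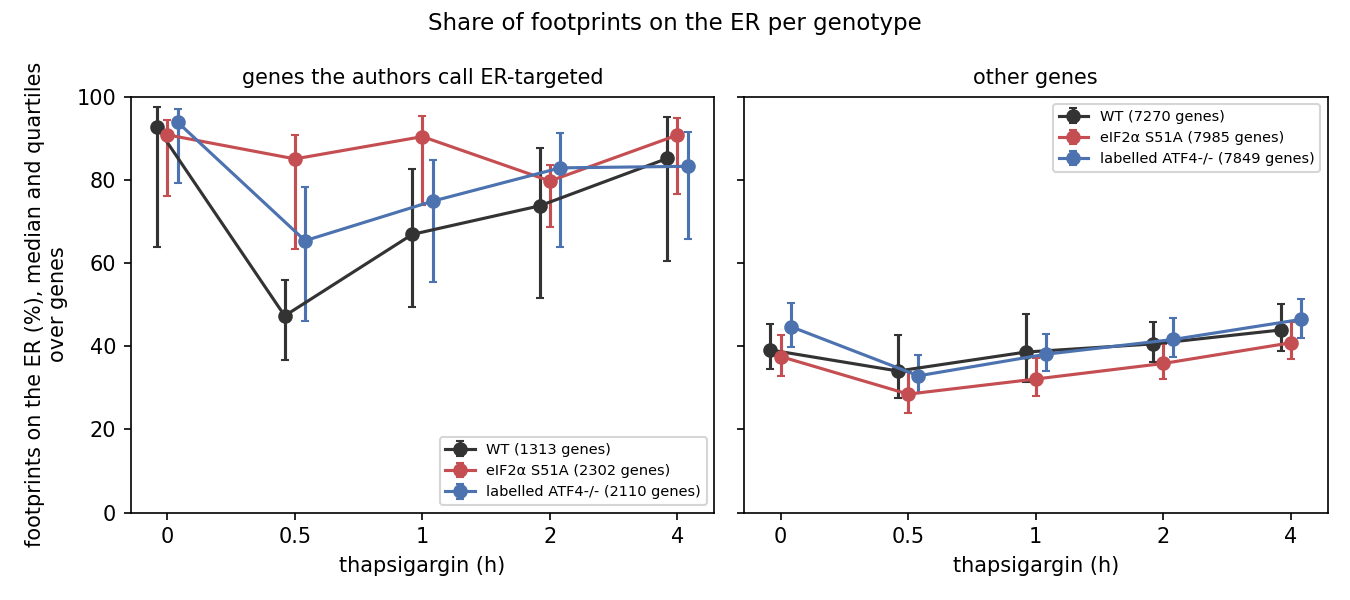
Share of footprints on the ER (percent, the authors' pooled values) against hours of thapsigargin, as the median over genes with quartiles as bars, for ER-targeted and other genes in WT, S51A and libraries labelled ATF4-/-. The ER-targeted median in WT was 92.6% at 0 h and 47.3% at 0.5 h, against 90.8% and 85.0% in S51A, each over its own set of genes. At 0.5 h ER-targeted genes held 5.34% of reads in WT cytosol library a and 15.6% in the shallow library b.

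At 1 h the ratio of ER to cytosol changed in WT for 1246 of 10419 genes, 185 higher and 1061 lower. ER-targeted genes made up 689 of the lower and 9 of the higher (870 and 21 adjusted over the list alone). Their median was −1.07 log2 against −0.06 for other genes (1.8e-21, and adjusted p = 0.22 with an estimated correlation), but with no filter on low values the difference was 0. Chaperones had 20 of 30 lower (23; 2.4e-10, and adjusted p = 0.45) and plasma membrane proteins 20 of 35 (20; 5.9e-12, and adjusted p = 0.55). Matrix and secreted proteins had 17 of 53 lower (24; 2.6e-09, and adjusted p = 0.76) and ER-Golgi transport 22 of 37 with 1 higher (25 and 1; 4.6e-12, and adjusted p = 0.076). Among genes with at least 20 predicted reads 289 passed, 9 higher and 280 lower, and voom called 688. In simulation 35.6% of calls were unchanged genes, 14.3% with the depth filter. The count was 2186 without ER 1 h library a, 677 without ER 1 h b, 776 and 704 without cytosol 0 h a and b, and 744 without ER 0 h b.

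In libraries labelled ATF4-/- 326 genes passed at 1 h, all lower, 246 of them ER-targeted (434 over the list alone; median −0.80 against −0.32; 2.4e-10, and adjusted p = 0.60 with an estimated correlation). With no filter on low values the difference of the medians turned from −0.48 to 0.15. Dnajb11, an ER cochaperone, stood at −3.87 ± 0.65 (adjusted p = 7.7e-04) and Cd9 at −3.24 ± 0.56. Transport genes had 18 of 37 lower (27; 1.7e-19, and 0.016). The counts were, for chaperones, 10 of 30 (22; 7.7e-14, and adjusted p = 0.27) and, for plasma membrane proteins, 8 of 35 (15; 9.3e-08, and adjusted p = 0.76). TMM-type scaling moved the median of all genes from −0.37 to 0.00 and left 82 genes, all lower, and voom called 102. The count was 135 and 95 without cytosol 1 h a and ER 1 h a, 173 and 131 without cytosol 0 h a and b, and 150 and 206 without ER 0 h a and b.

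In S51A limma called 0 genes at 1 h, 127 had an unadjusted p under 0.05, and voom called 3. The ER-targeted median was −0.11 against −0.28 for other genes, above them as a list (2.2e-13, and adjusted p = 0.48 with an estimated correlation). Over the 16 ways to take single libraries the difference ran from −0.15 to 0.48 and lay below 0 in 4. TMM-type scaling moved the median of all genes from −0.25 to 0.02. At 0.5 h 301 genes passed in S51A, all lower, with a median over all genes of −0.45. In WT 2252 passed then, 299 higher and 1953 lower (median −0.29), and in libraries labelled ATF4-/- 1460, all lower (−0.62). At 2 h 373 and 4 genes passed in WT and libraries labelled ATF4-/-, and at 4 h 18 and 8. In S51A limma called 0 at both times, where 363 and 128 had an unadjusted p under 0.05. No other tool or scaling was run on the shift at 0.5, 2 or 4 h. The share of the authors' footprint weight given to the ER, which acts on every gene alike, went from 49.5% to 36.6% at 0.5 h and 41.2% at 1 h in S51A. At 1 h it went from 47.0% to 39.9% in WT and from 48.3% to 38.9% in libraries labelled ATF4-/-. Counts and medians of the shift at both times hold that common move. The difference of the shift at 1 h from that of WT, a test added after seeing the data, passed for 189 genes in S51A, of which 170 were ER-targeted and higher and 2 ER-targeted and lower. The medians were 0.92 for ER-targeted and −0.22 for other genes (camera p = 1.5e-34, and p = 0.0044 with an estimated correlation). For libraries labelled ATF4-/- 2 genes passed, with medians of 0.22 and −0.26 (4.8e-11, and p = 0.11 with an estimated correlation).

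The same was asked of mRNA. In WT, over 910 ER-targeted genes the authors' median was 76.8% untreated, 44.8% at 0.5 h, 65.1% at 1 h, 67.4% at 2 h and 74.0% at 4 h, and over 4652 other genes 51.8%, 42.4%, 53.8%, 53.8% and 56.1%. At 1 h limma called 0 genes, 257 had an unadjusted p under 0.05, and voom called 0. ER-targeted genes lay below other genes as a list (median −0.40 against 0.20; 4.6e-05, 0 called, and adjusted p = 0.73 with an estimated correlation), as did chaperones (−1.82; 3.7e-07, 0 called, and adjusted p = 0.22). In S51A 974 genes passed, 17 higher and 957 lower, with a median over all genes of −2.17 log2 (−2.98 under TMM-type scaling). With voom that median was 0.99, all 6 calls were higher, and 55 of the 974 had the other sign. The count was 292 without ER 1 h library b, 595 and 1678 without cytosol 1 h a and ER 1 h a, 2282 and 272 without cytosol 0 h a and b, and 313 and 332 without ER 0 h a and b. In simulation all 5 calls were unchanged genes.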

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

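The test of WT material in the libraries labelled ATF4-/- was set up before its result was seen, as were all the genotype differences of footprint and mRNA changes, while the test of the difference in shift and the remaining tests of explanations in this part were chosen after the results they address were seen.

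Values stood out here because the change after thapsigargin differed between a genotype and WT by a test of that difference. In S51A the number of such genes was 1142 at 1 h and 833 at 4 h for footprints and 1 at 4 h for mRNA, and in libraries labelled ATF4-/- it was 69 and 204 for footprints. Each list below passed camera with the preset correlation, and the sign is that of the median difference from WT in log2.

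In S51A at 1 h the list medians were lower for NF-κB and cytokine genes (−1.23), immediate early genes (−1.03), ER chaperones (−0.99), ATF4-CHOP effectors (−0.80), upstream reading frame mRNAs (−0.70), plasma membrane proteins (−0.67), ER-Golgi transport (−0.60), extracellular matrix (−0.53) and ER-targeted genes (−0.22), and higher for ribosomal proteins (0.26). With an estimated correlation the NF-κB (adjusted p = 0.037) and upstream reading frame lists (0.035) still passed, and the others had adjusted p = 0.11 (immediate early), 0.88 (chaperones), 0.22 (ATF4-CHOP), 0.90 (plasma membrane), 0.88 (transport), 0.98 (matrix), 0.88 (ER-targeted) and 0.96 (ribosomal). Called members numbered 7 lower and 1 higher of 21 NF-κB genes (11 and 1 adjusted over the list alone), 15 lower and 3 higher of 30 immediate early genes (16 and 4), and 6 lower of 16 upstream reading frame mRNAs (7). For secretory lists passage between fractions in WT enters the difference.

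In S51A at 4 h ATF4-CHOP effectors stood at −1.92 (11 of 20 lower, 13 over the list alone), immediate early genes at −1.75 (19 lower and 1 higher of 30, 22 and 1), and NF-κB genes at −1.21 (8 of 21 lower, 12). Upstream reading frame mRNAs stood at −0.91 (7 of 16 lower, 8) and cytoskeleton genes at 0.96 (11 of 26 higher, 18). These 5 lists passed in both forms, with adjusted p = 0.0045, 0.0044, 0.017, 0.016 and 0.013 with an estimated correlation. Amino acid genes (−0.93, adjusted p = 0.25 with an estimated correlation), aminoacyl-tRNA synthetases (−0.67, 0.10), p53 targets (−0.48, 0.26), glycolysis (0.50, 0.34), muscle and myofibroblast markers (0.95, 0.17), mitotic genes (0.12, 0.84) and ribosomal proteins (0.14, 0.94) passed with the preset correlation alone. For mRNA at 4 h the medians were 1.98 for 5 neural markers, 1.51 for oxidative phosphorylation, 1.36 for cytoskeleton, 1.26 for mitotic genes and 0.90 for ribosomal proteins. They were 0.13 for ER-targeted genes, −0.45 for amino acid genes, −0.17 for immediate early genes and −0.46 for NF-κB genes, over a median of all genes of 0.45 (0.83 under TMM-type scaling). With voom that median was −0.55, so these values are not to be read against 0, and lists were tested only against other genes. None of these mRNA lists passed with an estimated correlation, where adjusted p lay between 0.15 for amino acid genes and 0.94 for ER-targeted genes.

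In libraries labelled ATF4-/- cholesterol genes stood at 0.84 at 1 h (0 called, 5 over the list alone, and adjusted p = 0.41 with an estimated correlation). At 4 h the medians were 0.18 for amino acid genes, 0.49 for cytoskeleton, 0.34 for glycolysis, 0.28 for ER-Golgi transport, −0.19 for heat shock proteins and −0.37 for immediate early genes. ER-targeted genes stood at 0.10, and none of these lists passed with an estimated correlation, where adjusted p was 0.88, 0.18, 0.63, 0.55, 0.39, 0.54 and 0.97 in that order. The difference in shift at 1 h between S51A and WT had a median of 0.92 over ER-targeted genes.

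A first pattern was the fall of the ER to cytosol footprint ratio of ER-targeted genes at 1 h in WT and in libraries labelled ATF4-/-. The authors' weighting of the fractions moves all genes alike, yet the difference between ER-targeted and other genes lay below 0 in all 16 ways to take single libraries in both genotypes (highest −0.25). It stayed below 0 among genes with at least 20 predicted reads (highest −0.59), which may still lie near the minimum in untreated cytosol. With no filter it was 0.15 in libraries labelled ATF4-/- and 0 in WT, so depth and the read minimum stay open. An equal leak of ER content into the cytosol fraction would put a like share of every ER-targeted gene there, but in WT at 1 h the 10th percentile over 1155 such genes was 8.53% against a median of 25.2%. A leak that differs between genes, through stress acting on the membrane or its solubility, stays open, and so does the hypothesis that ribosomes may leave the ER upon eIF2α phosphorylation, as S51A differed from WT at 1 h.

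A second pattern was the rise of ATF4-CHOP and amino acid genes in libraries labelled ATF4-/-. WT material mixed into them would have to make up 59.6% for the median of 21 members called in both genotypes (12.01% for the lowest), whereas the 10 lowest of 1655 genes at 100 RPKM or more in WT at 4 h had a median of 0.115% of the WT level. Scaling was tested over 44 members, whose median rise was 0.94 log2 against 0.16 for the median of all genes plus the largest scaling difference. A mislabelled sample was not tested beyond this, and what the allele lacks stays open, so the rise neither shows nor excludes induction without ATF4.

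The last pattern was the high level of immediate early genes in untreated S51A libraries. A single library is argued against, since the lowest untreated library lay 1.76 log2 above the highest library of 4 h in the list median, in the fraction where the gap was smaller. Handling of the untreated plates alone would leave the libraries of 0.5 h near those of 4 h, but the list stood at −0.17 at 0.5 h, −0.04 at 1 h, −0.90 at 2 h and −1.85 at 4 h. Handling thus stays open, as do growth conditions shared by all S51A plates, the cell line's history and the genotype. The design holds 1 line per genotype by its labels and cannot separate these.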

How the results depend on the processing

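The alternatives voom, read filter and leaving out the shallow libraries were added after seeing the data. The rest were planned. No paired analysis was possible because the recovered libraries carry no replicate numbers, so the replicate blocks were not run, nor the one that renumbers the WT ER untreated mRNA libraries. The 7 comparisons of mRNA from libraries labelled ATF4-/- were not tested. The filter of 20 predicted reads left under 100 genes, and gave no value, for the comparisons that use S51A mRNA. For the counts below the cause was not tested, except that a left-out library leaves fewer samples and the read filter fewer genes. Depth limits most of all the mRNA comparisons and WT at 1 h.

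Of 793 calls of named genes none changed direction under any alternative. Calls kept numbered 724 with TMM-type rescaling, 752 with no filter on low values, 748 with a pseudocount of 0.25, 649 with voom, 551 of 551 with the read filter, 736 with the shallow libraries left out, and 6652 of 7824 over single libraries left out. Of 181 list calls 163, 158 and 175 were kept under the first 3, 123 of 135 with the read filter, 159 without the shallow libraries and 1646 of 1840 over single libraries left out. For 10 list, gene or ER-targeted values the direction turned, for some lists only against other genes. In the shift at 1 h in libraries labelled ATF4-/-, aminoacyl-tRNA synthetases went from −0.48 to 0.0025 under TMM-type rescaling, and ER-targeted minus other genes from −0.48 to 0.15 with no filter. Cholesterol genes in the WT shift went from −0.94 to −0.58 with the read filter and turned above other genes by camera. Without the shallow libraries ribosomal proteins in S51A at 1 h went to −0.068 for mRNA and 0.17 for efficiency, and Atf4 mRNA in untreated S51A from −0.23 to 1.61. In the S51A shift, extracellular matrix stood at −0.30 without ER 1 h library a (lowest and highest over single libraries −0.43 and 0.27). Without cytosol 0 h library b, cholesterol stood at −0.35 (−0.35 and 0.31), ER-associated degradation at −0.34 (−0.34 and 0.20) and plasma membrane at −0.54 (−0.54 and 0.44), each then below other genes.

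Counts that moved by over 1.5 times were as follows. Footprints at 1 h: WT 3006, 1147 with the read filter; S51A 39, 76 with no filter, 164 with voom, 87 without the shallow libraries; libraries labelled ATF4-/- 1289, 1960 with voom, 2050 without the shallow libraries. At 4 h: WT 1836, 2832 without the shallow libraries; S51A 857, 1918 with voom, 1418 without the shallow libraries; libraries labelled ATF4-/- 1643, 2598 and 2470 in that order. Leaving the shallow WT and mRNA libraries out also moves comparisons that do not use them, since all share 1 estimate of the spread.

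Differences from WT: S51A at 1 h 1142, 607 with the read filter, 1794 without the shallow libraries, and at 4 h 833, 1535 without the shallow libraries; libraries labelled ATF4-/- at 1 h 69, 16 with voom, 43 with the read filter, 307 without the shallow libraries, and at 4 h 204, 545 without them. Shift at 1 h: WT 1246, 688 with voom, 289 with the read filter; S51A 0, 18 with no filter, 3 with voom; libraries labelled ATF4-/- 326, 82 with TMM-type rescaling, 102 with voom, 710 without the shallow libraries. The median of ER-targeted minus other genes was −1.019 in WT, 0 with no filter and −2.86 with voom, and in libraries labelled ATF4-/- −0.48, then −0.72 with TMM-type rescaling, −0.87 with the pseudocount, −1.50 with voom and −0.90 with the read filter.

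WT mRNA: 0 at 1 h, 79 with no filter; 7 at 4 h, 196 with no filter, 2 with the pseudocount, 4 with voom, 1 with the read filter, 26 without the shallow libraries. WT efficiency: 6 at 1 h, 29 with TMM-type rescaling, 141 with no filter, 3 with voom, 1 with the read filter, 17 without the shallow libraries; 0 at 4 h, 9 with TMM-type rescaling, 310 with no filter, 1 with the pseudocount, 8 without the shallow libraries. WT mRNA shift: 0, 3 with TMM-type rescaling, 92 with no filter.

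S51A mRNA at 1 h: 7, 2 with TMM-type rescaling, 17 with no filter, 4 with the pseudocount, 15 with voom, 240 without the shallow libraries (83 higher, 157 lower). At 4 h: 6, 21 with no filter, 51 with voom (16 and 35), 204 without the shallow libraries (170 and 34). Its difference from WT: 1, 0 with TMM-type rescaling or the pseudocount, 53 with no filter, 3 with voom, 34 without the shallow libraries. Efficiency at 1 h: 46, 24 with TMM-type rescaling, 12 with voom, 892 without the shallow libraries, and at 4 h 110, 69 with no filter, 17 with voom, 509 without them. mRNA shift: 974, 6 with voom, 383 without the shallow libraries. Untreated against WT: 530, 1078 with TMM-type rescaling (67 higher, 1011 lower), 865 with voom (452 and 413), 1554 without the shallow libraries (897 and 657). TMM-type rescaling moved the median of all genes from 0.62 to 0.94 for S51A mRNA at 4 h (−0.41 with voom), from 0.19 to 0.29 for its efficiency at 1 h, and from 0.07 to 0.28 for the WT mRNA shift. With voom it turned from −2.17 to 0.99 (S51A mRNA shift), −0.73 to 0.38 and 0.19 to −0.15 (S51A efficiency, 4 h and 1 h), and −0.21 to 0.23 and 0.26 (S51A mRNA, 1 h and untreated), and for the footprint shift from −0.19 to 0.17 (WT), −0.25 to 0.17 (S51A) and −0.37 to 0.03 (libraries labelled ATF4-/-).

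With each library left out in turn, where a group of 1 is assumed to vary like the others, the lowest and highest footprint counts were 2042 and 3454 (WT 1 h), 20 and 44 (S51A 1 h) and 824 and 1097 (libraries labelled ATF4-/- 1 h). At 4 h they were 1240 and 1597 (WT), 420 and 740 (S51A) and 1165 and 1324 (libraries labelled ATF4-/-). For differences from WT they were 735 and 1727 (S51A 1 h), 561 and 833 (S51A 4 h), 27 and 712 (libraries labelled ATF4-/- 1 h) and 104 and 208 (4 h). For shifts they were 677 and 2186 (WT), 0 and 0 (S51A), and 95 and 234 (libraries labelled ATF4-/-). In WT they were 0 and 1 for mRNA at 1 h, 2 and 6 at 4 h, 1 and 14 for efficiency at 1 h, 0 and 3 at 4 h, and 0 and 0 for the mRNA shift. In S51A they were 1 and 480 for mRNA at 1 h, 2 and 670 at 4 h, and 0 and 102 for its difference from WT. They were 19 and 769 for efficiency at 1 h, 8 and 1629 at 4 h, 272 and 2282 for the mRNA shift, and 204 and 919 for untreated cells against WT.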

Other observations

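The test of coding length and the search for genes near 0 in libraries labelled ATF4-/- were set up before their results were seen, but the genes named from that search were chosen after their values were seen.

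Some inflammatory and interferon genes that were abundant in WT were close to absent in libraries labelled ATF4-/-. In the authors' pooled footprint totals at 4 h, the acute phase gene Saa3 was at 914 RPKM in WT and 0.220 RPKM in libraries labelled ATF4-/-, the chemokine Cxcl5 at 2009 and 0.638 RPKM. The interferon-induced gene Usp18 was at 245 and 0.1999 RPKM and the interferon-induced gene Ifit3 at 223 and 0.646 RPKM. The chemokine genes Ppbp (796 and 2.09 RPKM) and Ccl20 (378 and 0.685 RPKM), the cytokine Tslp (517 and 0.925 RPKM), the protease Mmp3 (133 and 0.133 RPKM), Enpp2 (138 and 0.0371 RPKM) and Phf11d (142 and 0.184 RPKM) made up the rest of the 10 lowest ratios among 1655 genes at 100 RPKM or more in WT. These pooled totals carry no error, and the difference was not tested.

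The share on the ER of genes that are not ER-targeted was also lowest at 0.5 h. In S51A the median over 7985 such genes was 37.5% untreated, 28.5% at 0.5 h, 32.1% at 1 h, 35.8% at 2 h and 40.8% at 4 h in the authors' values. In libraries labelled ATF4-/- (7849 genes) it was 44.7%, 32.9%, 38.1%, 41.6% and 46.4%. The ER share of the authors' footprint weight was 36.6% at 0.5 h and 48.7% at 4 h in S51A, 35.8% and 47.9% in libraries labelled ATF4-/-, and 34.7% and 48.9% in WT.

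Long coding sequences hold more ribosomes, so they might keep an mRNA on the ER for longer and show a smaller fall of the ER to cytosol ratio at 1 h. Across ER-targeted genes with at least 20 predicted reads, Spearman's rho between coding length and the change of the ratio was −0.23 in WT (182 genes, permutation p = 0.0018), where above 0.1 would have been needed, and Pearson's r was −0.05. In libraries labelled ATF4-/- rho was 0.12 (988 genes, p = 1.2e-04, r = 0.22), and in S51A −0.19 (1668 genes, p = 1e-05, the smallest that 100000 permutations can give, r = −0.33). The idea thus failed in WT, with the other sign. The effects of length and level were not separated. These are correlations across genes, which are not independent replicates, and the 3 were computed as 1 family.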
